A study of Mus musculus with 17 samples.

How the data were processed

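The 17 libraries came from locus coeruleus tissue of male C57BL/6 mice, per the labels. The mice received vindeburnol or VB-127 at 20 mg/kg once daily by oral gavage for 5 days or were untreated, and tissue was taken 24 hours after treatment. No group is labelled as given gavage without a compound. A difference from controls therefore cannot be told apart from an effect of the gavage. Libraries of poly(A) RNA were made with a kit that keeps strand, per the labels' protocols; whether counting used strand is not given in the sources used here. Reads were aligned with STAR to GRCm39 and quantified with Salmon, per the submitters' processing notes. The deposited values are TPM (transcripts scaled to the same total in every library) for 78298 genes in each library. TPM carries no read depth, so the depth of each library is unknown and no interval that needs it is given. Every value therefore rests on the spread between libraries.

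Values were analysed as log2(TPM + 1), with a pseudocount of 1, so a fold change is on that scale and understates the change of genes with low values. A gene was tested if it reached 1 TPM in at least 5 libraries, which left 16153 genes. A gene-wise linear model in limma 3.58.1 (R 4.3.3; eBayes with trend and robust moderation) was fitted to all 17 libraries with group as the only term, since the 3 groups then share 1 estimate of spread. Each of the 3 comparisons was two-sided, with Benjamini-Hochberg adjustment over the genes tested and a call at an adjusted p under 0.05. The labels do not say that each library came from a separate animal, so the p-values measure the spread between samples. Replicate numbers are not stated to mark a shared animal, litter or day and were not part of the fit.

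The tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined, except where a choice is said to have been added later. Of 39 gene lists for cell types and pathways, 38 had at least 3 tested members. They were tested with camera in limma at its preset correlation of 0.01, adjusted over the lists in a comparison. This test asks whether the genes of a list lie above or below the other genes, so a list with a mean near 0 can be called lower when most other genes lie above 0. Camera with an estimated correlation and fry, which tests whether a list moves on balance 1 way, stood beside it. An exact permutation test of each list's mean per library, and 4 marker lists, were added after the data were seen. Single measures per library were compared with a two-sided exact permutation test in a family of 30 comparisons, chosen after the data were seen. The smallest p this test can give is 0.00216.

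The named genes were, per comparison and direction, the called genes with the smallest p or largest fold change among those with a mean of at least 2 TPM and a symbol that is not a predicted name. Where fewer than 6 were called, genes with the smallest p filled the number up to 6 and are described as not past the threshold. A further 12 genes of monoamine neurons, glia and activity were taken in every comparison, along with up to 4 members of each called list; some genes that the rule takes are not reported here. Gm28119, Lcn2 in single libraries, and the marker genes of tissue content were named after their values were seen. Symbols are those the files pair with gene identifiers. Of 78298 identifiers, 51498 were found in GENCODE M21, which was used for gene types alone because its build differs from that of the files; no coordinates are given.

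The fit was tested on simulated data drawn for the 16153 genes, with 50 genes changed per fold. At 2-fold it recovered 86.0% for vindeburnol against controls, 94.0% for VB-127 against controls and 86.0% for vindeburnol against VB-127. At 1.5-fold it recovered 48.0%, 66.0% and 46.0% in the same order, and the false share among calls was 5.14%, 5.35% and 5.65%. The simulated genes were drawn independently, without structure shared between libraries, and changes were added on the log2(TPM + 1) scale. Many genes were changed at once, which eases the adjusted threshold. The recovery therefore does not measure what was missed in the real data, where few genes were called. Alternatives covered the pseudocount, filter, scaling, library weights, moderation, covariates, a replicate block, the groups in the fit and each library left out in turn. The agreement of the compounds was set beside 100 simulations of unchanged groups that shared a set of controls. Each simulation shuffled the deviations of all 17 libraries from their group means, so the simulated controls were not the real ones. In addition, 100 random regroupings were drawn per comparison. A second table with the same values for all libraries was not used here.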

Results

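Gene expression was measured as TPM in 5 libraries from mice given vindeburnol, 6 from mice given VB-127 and 6 from untreated controls. Vindeburnol is a synthetic relative of the vinca alkaloids, and the labels describe VB-127 as a derivative of it. The series title asks for the molecular target of these compounds. Read depth is unknown, and between 21016 and 26993 genes had a value above 0 in a library. Bc1, a short neuronal non-coding RNA, took 16.1% to 35.3% of the TPM total of a library, with means of 24.5% ± 5.90 in controls (SD, n = 6), 21.4% ± 5.89 after vindeburnol (SD, n = 5) and 21.04% ± 4.41 after VB-127 (SD, n = 6).

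The labels name locus coeruleus tissue, yet over the 17 libraries Dbh and Slc6a2, used by noradrenergic neurons, had medians of 1.08 and 0.300 TPM. Slc6a3, Tph2, Cartpt and Ucn, of dopaminergic, serotonergic and peptide neurons, had medians of 45.5, 74.2, 204 and 28.5 TPM. Dbh, the enzyme that makes noradrenaline, was at 18.9 and 12.3 TPM in control replicates 1 and 6 and at 0.290 to 2.57 TPM in the other controls. It was at 0 to 1.72 TPM after vindeburnol and 0 to 2.36 TPM after VB-127. The noradrenaline transporter gene Slc6a2 reached 8.94 TPM in control replicate 1 and did not pass the filter for testing. Slc6a3, the dopamine transporter gene, was at 1.04 TPM in control replicate 1 and reached 124 TPM in a VB-127 library. Tph2, which serotonergic neurons use to make serotonin, ranged from 1.08 to 129 TPM, and Cartpt, a neuropeptide gene, from 17.6 to 301 TPM. In exact permutation tests of Dbh against controls the p was 0.141 after vindeburnol (n = 5 and 6, adjusted p 0.455) and 0.110 after VB-127 (n = 6 and 6, adjusted p 0.455).

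**Figure D1:**
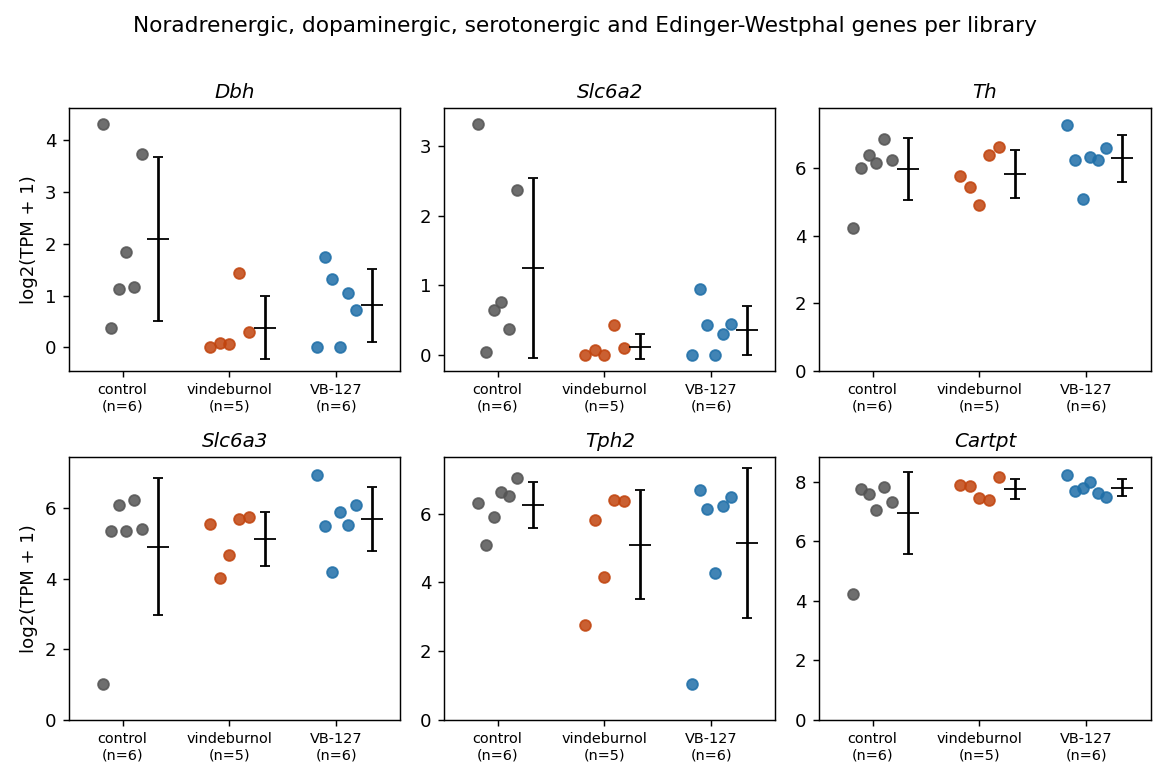
Level of 6 marker genes of monoamine and peptide neurons in each library as log2(TPM + 1), by group; each point is a library, the bar is the mean and the error bar 1 SD. Control replicates 1 and 6 hold the highest Dbh, at 18.9 and 12.3 TPM.

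Vindeburnol was compared with untreated controls to ask which transcripts differ after 5 days of dosing. The transcription factor gene Npas3 had the smallest p, at 10.2 ± 1.76 TPM after vindeburnol (SD, n = 5) against 4.98 ± 0.891 TPM in controls (SD, n = 6). All 5 treated libraries, from 8.28 to 12.3 TPM, lay above the highest control at 5.72 TPM. Its log2 difference was 0.90 (SE 0.14, 95% interval 0.60 to 1.20), with an adjusted p of 0.0641 that missed the threshold. Genes that respond to glucocorticoid hormones lay higher on average without passing with an estimated correlation (adjusted p = 0.301), led by the kinase gene Sgk1 at 106 ± 52.2 against 42.4 ± 12.4 TPM. The list's mean level was 5.80 and 5.43 in vindeburnol replicates 1 and 3, 4.44 to 4.93 in the other 3 and 4.02 to 4.87 in controls. Vindeburnol replicate 3 also stood apart for some cerebellar markers, with Pcp2 at 20.3 TPM against 0 to 4.88 and Gabra6 at 2.38 TPM against 0 to 0.310 in the other 16 libraries. Its mean level of the Purkinje list was 4.34 against 3.29 to 4.01. The granule cell list, at 3.70, lay within the 3.01 to 3.71 of the others. The stress chaperone gene Hspa1b, the acetylcholine synthesis gene Chat and the astrocyte filament gene Gfap lay lower, with log2 differences of -1.11, -0.998 and -0.59 and adjusted p of 0.487, 0.450 and 0.454.

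No gene passed the test for vindeburnol against controls: limma called 0 of 16153 genes, and 1319 had an unadjusted p under 0.05, where 5% of the genes is 808. Of these, 1122 were higher and 197 lower (85.1% higher), while median-ratio scaling gave 51.9% higher and quantile normalization 47.7%. Random regroupings of these libraries gave a median of 819 genes at that unadjusted p, and the real groups with library weights gave 808. Library weights in limma called 1 gene, Npas3, at an adjusted p of 0.0462, within a range of 0.0216 to 0.517 over its alternatives. Beta-actin (Actb) was at 697 ± 29.3 against 544 ± 52.0 TPM, a log2 difference of 0.36 with an adjusted p of 0.209, higher in 5 of 5 libraries than the control mean. Tmem91, the sphingomyelinase gene Smpd2, the adhesion receptor gene Adgrb2 and the cilium gene Cfap69 had log2 differences of 0.50, 0.51, 0.43 and 0.94, each with an adjusted p of 0.211 and higher in 5 of 5 libraries. On the lower side, the cytochrome oxidase gene Cox8b, the myeloid gene Ly86, the complex I gene mt-Nd3, the hypoxia-induced lipid droplet gene Hilpda and the endoplasmic reticulum gene Sdf2l1 had log2 differences of -1.21, -0.59, -0.57, -0.47 and -0.52. Their adjusted p lay between 0.352 and 0.433, and 0 of 5 libraries exceeded the control mean for any of them.

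Among genes of monoamine neurons and activity, none passed the test for vindeburnol against controls. Dbh differed by -1.71 (95% interval -2.999 to -0.43, adjusted p 0.516). A fit to Dbh alone, without moderation, gave an interval of -3.12 to -0.30 with all libraries and a difference of -0.75 (95% interval -1.69 to 0.20) without control replicates 1 and 6. The neuropeptide gene Gal, the vesicular transporter gene Slc18a2 and the decarboxylase gene Ddc had log2 differences of -0.87, -0.66 and -0.47 with adjusted p of 0.507, 0.604 and 0.6249. Tyrosine hydroxylase, encoded by Th, was at 61.4 ± 28.9 against 71.1 ± 32.1 TPM (log2 difference -0.16, 95% interval -1.15 to 0.84, adjusted p 0.956). Its difference was 0.02 without control replicate 5, 0.08 without vindeburnol replicate 3 and -0.51 without control replicate 1. Th was lowest in control replicate 1, at 17.8 TPM, where Dbh was highest and Slc6a3 lowest, at 18.9 and 1.04 TPM. It was highest in VB-127 replicate 1, at 154 TPM, where Slc6a3 was at 124 TPM and Dbh at 0. The Th values of all 3 comparisons therefore cannot be read as those of noradrenergic neurons alone. The values for the immediate early gene Fos, the growth factor gene Bdnf, the myelin gene Mbp and the choroid plexus gene Ttr were -0.22, -0.06, -0.12 and 0.31, with adjusted p of 0.865, 0.946, 0.810 and 0.788. The median log2 difference of all genes was 0.08 for vindeburnol against controls.

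Camera with the preset correlation called 17 of 38 lists for vindeburnol against controls, 4 higher and 13 lower. An estimated correlation called 0, fry 0 and the exact permutation test 0, and in every list 0 members passed over all genes. All 14 tested glucocorticoid-responsive genes were higher in value, with a mean log2 difference of 0.57, 9 at an unadjusted p under 0.05 and 7 adjusted over the list alone (adjusted p = 0.301 with an estimated correlation). Sgk1, the transcription factor gene Zbtb16, the arrestin-domain gene Arrdc2 and the NF-kappaB inhibitor gene Nfkbia had log2 differences of 1.22, 1.01, 0.91 and 0.84, with adjusted p of 0.507, 0.491, 0.454 and 0.425. Circadian clock genes had a mean of 0.26 with all 15 higher in value and 1 adjusted over the list alone (adjusted p = 0.405 with an estimated correlation), with Per1, Per2, Nr1d1 and Cry2 at 0.65, 0.42, 0.35 and 0.25. The 5 erythrocyte genes had a mean of 0.48 with 3 adjusted over the list alone (adjusted p = 0.371 with an estimated correlation); Alas2 was at 0.55, and Hba-a1 and Hba-a2, near-identical copies whose reads are uncertain, at 0.49 and 0.57. Sodium and calcium channel genes had a mean of 0.26 with 0 adjusted over the list alone (adjusted p = 0.593 with an estimated correlation), with the T-type channel genes Cacna1g and Cacna1h at 0.76 and 0.44 and the L-type gene Cacna1d at 0.54; without control replicate 4 the mean was 0.15.

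Lists called lower after vindeburnol covered chaperones, neurons, glia, vessels and mitochondria. Heat shock and unfolded protein genes had a mean of -0.22 with 2 of 16 adjusted over the list alone (adjusted p = 0.301 with an estimated correlation), led by Sdf2l1, Hspa1b and Manf, the last at -0.31; without vindeburnol replicate 3 the mean was -0.13. Hspa1b has a near-identical copy in Hspa1a, so its reads are uncertain. Noradrenergic genes had a mean of -0.35 with 0 of 11 adjusted over the list alone (adjusted p = 0.266 with an estimated correlation); 3 were lower and 1, Tfap2b at 0.85, higher at an unadjusted p under 0.05. Cholinergic genes had a mean of -0.54 with 1 of 4 adjusted over the list alone (adjusted p = 0.301 with an estimated correlation), with Chat at -0.998 and the choline transporter gene Slc5a7 at -0.76. Serotonergic genes had a mean of -0.35 with 0 adjusted over the list alone (adjusted p = 0.405 with an estimated correlation), with Tph2 at -1.15. Without vindeburnol replicate 1 the serotonergic mean was -0.14 and without replicate 3 it was -0.21. Parabrachial neuropeptide genes had a mean of -0.05 with 0 adjusted over the list alone (adjusted p = 0.301 with an estimated correlation); Pdyn was at -0.48 and Tac1 at 0.47, and the mean was -0.00064 without control replicate 1 and -0.11 without control replicate 4.

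Microglial genes had a mean of -0.16 after vindeburnol and reactive microglial and MHC genes a mean of -0.20, each with 0 adjusted over the list alone (adjusted p = 0.301 and adjusted p = 0.270 with an estimated correlation). The lysosomal protease gene Ctss, Aif1, the MHC chaperone gene Cd74 and Spp1 were at -0.38, -0.42, -0.55 and -0.67. Of the inflammatory mediators 5 of 15 were tested, and their mean of -0.65 and median of 0.02 differed in sign, with 2 adjusted over the list alone (adjusted p = 0.301 with an estimated correlation). Those members were the acute-phase gene Lcn2, at 2.85 ± 2.04 against 42.0 ± 47.3 TPM, and the chemokine gene Ccl12, at 0.628 ± 0.465 against 2.41 ± 1.21 TPM. Endothelial and ependymal genes had means of -0.18 and -0.18 with 0 adjusted over the list alone in either (adjusted p = 0.301 and adjusted p = 0.405 with an estimated correlation); the tight junction gene Cldn5 was at -0.55 and the glucose transporter gene Slc2a1 at 0.35. The endothelial mean was -0.11 without control replicate 6 and -0.10 without vindeburnol replicate 3. The ependymal mean was -0.0043 without vindeburnol replicate 1, -0.09 without control replicate 5 or vindeburnol replicate 2, and -0.29 to -0.31 without control replicate 6 or vindeburnol replicate 3 or 4. Nuclear-encoded respiratory chain, mitochondrially encoded and cytosolic ribosomal genes had means of -0.06, -0.06 and -0.01 (adjusted p = 0.405, 0.578 and 0.695 with an estimated correlation). Adjusted over the list alone, 0, 1 and 0 of them passed, the 1 being mt-Nd3; mt-Co2, at -0.05, changed sign with scaling and without control replicate 6. With 1 library left out these 3 means ran from -0.09 to -0.02, from -0.17 to 0.03 and from -0.03 to 0.04, with extremes without vindeburnol replicate 5 and control replicate 5, control replicates 4 and 6, and control replicates 6 and 5. The glucocorticoid call was lost without vindeburnol replicates 1 and 3 and with noradrenergic, myelin and granule cell covariates. In a fit to the list mean the difference went from 0.57 (SE 0.22, 95% interval 0.10 to 1.04) to 0.21 (SE 0.18, 95% interval -0.18 to 0.60) and 0.35 (SE 0.24, 95% interval -0.18 to 0.87), so the mean fell while its SE changed little. With cerebellar granule and Purkinje lists as covariates, chosen after the data were seen, it was 0.47 (95% interval -0.06 to 0.99).

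**Figure D2:**
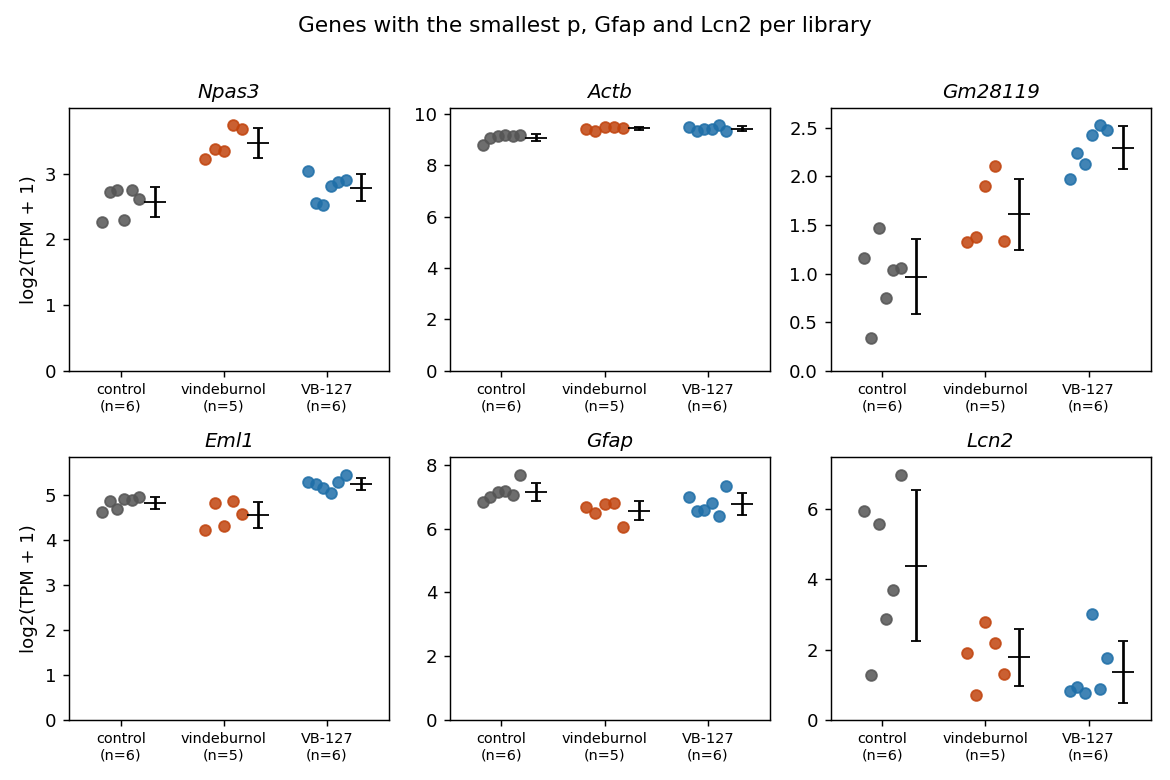
Level of 6 genes in each library as log2(TPM + 1), by group; each point is a library, the bar is the mean and the error bar 1 SD. Npas3 after vindeburnol lay between 8.28 and 12.3 TPM and in controls up to 5.72 TPM.

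VB-127 was compared with untreated controls to ask which transcripts differ after 5 days of the derivative. The predicted gene Gm28119 passed the test, at 3.95 ± 0.729 TPM after VB-127 (SD, n = 6) against 1.01 ± 0.512 TPM in controls (SD, n = 6). It was higher in 6 of 6 libraries than the control mean, with a log2 difference of 1.33 (SE 0.19, 95% interval 0.93 to 1.73) and an adjusted p of 0.0157. Actb was at 692 ± 42.6 against 544 ± 52.0 TPM, a log2 difference of 0.35 in 6 of 6 libraries with an adjusted p of 0.171. The acute-phase gene Lcn2 was at 2.09 ± 2.49 against 42.0 ± 47.3 TPM, a log2 difference of -3.04 with an adjusted p of 0.461.

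Gm28119 was the only gene that limma called for VB-127 against controls, and 1648 genes had an unadjusted p under 0.05, where 5% of the genes is 808. Of these, 1562 were higher and 86 lower (94.8% higher), while median-ratio scaling, which moved the median of all genes from 0.11 to 0.01, gave 53.1% higher and quantile normalization 46.5%. Random regroupings of these libraries gave a median of 510 genes at that unadjusted p. The real groups with noradrenergic, myelin and granule cell covariates gave 790. GENCODE M21 lists Gm28119 as a transcript within an intron on the same strand as its host, so reads of its host cannot be told apart from its own. The call was lost without VB-127 replicate 4, 5 or 6, with adjusted p of 0.0728, 0.0803 and 0.0777, and without control replicate 4 or 5, with adjusted p of 0.0639 and 0.0509, within a range of 0.00709 to 0.105 over its alternatives. Not past the threshold, Slc7a10, an amino acid transporter gene, was at 0.44, Ift140, of intraflagellar transport, at 0.52, Zfp781a at 0.96 and Adgrb2 at 0.35. Their adjusted p ranged from 0.363 to 0.454, with 6 of 6 libraries above the control mean. On the lower side, Akip1, Chat, the melanocortin receptor accessory gene Mrap2, the spliceosome gene Snrpe and Ndufb4c, a copy whose reads are uncertain, were at -0.53, -0.83, -0.44, -0.22 and -0.40, each with an adjusted p of 0.461.

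None of the genes of monoamine neurons, glia and activity passed the test for VB-127 against controls. Dbh was at -1.28 (95% interval -2.51 to -0.06, adjusted p 0.483). The fit to Dbh alone gave an interval of -2.62 to 0.06 with all libraries and a difference of -0.32 (95% interval -1.23 to 0.60) without control replicates 1 and 6. Th was at 0.31 (95% interval -0.63 to 1.26, adjusted p 0.798), from 85.3 ± 39.4 against 71.1 ± 32.1 TPM, and turned to -0.04 without control replicate 1. This Th difference, too, cannot be read as that of noradrenergic neurons alone. Gal, Slc18a2 and Ddc were at -0.76, -0.09 and -0.07, with adjusted p of 0.468, 0.912 and 0.913. Slc18a2 turned to 0.03 without control replicate 6, and Ddc turned to between 0.0076 and 0.019 without control replicate 5 or VB-127 replicate 3 or 4. Gfap, Fos and Ttr were at -0.38, 0.26 and 0.47, with adjusted p of 0.470, 0.727 and 0.547. Mbp and Bdnf were at 0.11 and 0.10, both of which turned negative with median-ratio scaling, and had adjusted p of 0.711 and 0.799.

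Camera with the preset correlation called 9 of 38 lists for VB-127 against controls, 1 higher and 8 lower, and an estimated correlation called 0, fry 0 and the exact permutation test 0. In every list 0 members passed over all genes, and without control replicate 3 the preset count was 14. Erythrocyte genes had a mean of 0.43 with 0 of 5 adjusted over the list alone (adjusted p = 0.642 with an estimated correlation), with Hba-a2 at 0.59 and Hbb-bs at 0.40. Glucocorticoid-responsive genes had a mean of -0.14 with 0 of 14 adjusted over the list alone (adjusted p = 0.585 with an estimated correlation); the metallothionein genes Mt1 and Mt2, the sulfotransferase gene Sult1a1 and the lipid droplet gene Plin4 were at -0.27, -0.30, -0.46 and -0.84. The list mean was -0.24 without control replicate 4 and -0.07 without control replicate 6. Heat shock and unfolded protein genes had a mean of -0.11 with 0 of 16 adjusted over the list alone (adjusted p = 0.585 with an estimated correlation), with Hspa1b at -0.77 and Sdf2l1 at -0.36; without VB-127 replicate 1 the mean was -0.069. Cholinergic and serotonergic genes had means of -0.38 and -0.30 with 1 and 0 adjusted over the list alone (adjusted p = 0.585 with an estimated correlation for both). Without VB-127 replicate 1 the serotonergic mean was -0.05, and without control replicate 6 the cholinergic mean was -0.21. Noradrenergic genes had a mean of -0.12 with 0 adjusted over the list alone (adjusted p = 0.585 with an estimated correlation), with Gal and Dbh lower and the pteridine reductase gene Qdpr, at 0.20, higher at an unadjusted p under 0.05; the mean was -0.06 without control replicate 6 and -0.07 without VB-127 replicate 4. Microglial genes had a mean of -0.07 (-0.13 without control replicate 4 and -0.02 without control replicate 6), with Ctss at -0.26 and P2ry12 at 0.32, and 0 adjusted over the list alone (adjusted p = 0.585 with an estimated correlation). Mitochondrially encoded genes had a mean of -0.03 and a median of 0.01, which differ in sign, and ependymal genes a mean of -0.0037, with 0 adjusted over the list alone in both (adjusted p = 0.666 and 0.739 with an estimated correlation). With 1 library left out these 2 means ran from -0.14 to 0.06, the extremes without control replicates 4 and 6, and from -0.13 to 0.09, the extremes without control replicates 6 and 5.

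Vindeburnol and VB-127, given at the same dose and for the same time, were compared directly to ask where the compounds differ. Glucocorticoid-responsive genes lay higher after vindeburnol, with a mean log2 difference over 14 genes of 0.71 (95% interval 0.24 to 1.18). The cell cycle inhibitor gene Cdkn1a was at 35.9 ± 28.8 TPM after vindeburnol (SD, n = 5) against 8.56 ± 1.74 TPM after VB-127 (SD, n = 6), and Sgk1 at 106 ± 52.2 against 44.3 ± 25.6 TPM. In vindeburnol replicates 1 and 3 Cdkn1a was at 73.2 and 60.9 TPM. It was at 13.7 to 17.2 TPM in the other vindeburnol libraries, up to 11.9 TPM after VB-127 and 8.77 to 28.2 TPM in controls. Endothelial, immediate early and myelin genes lay lower after vindeburnol, with means of -0.28, -0.26 and -0.23 that did not pass with an estimated correlation (adjusted p = 0.5004, 0.5004 and 0.560). The microtubule-associated gene Eml1 had the smallest p, at 23.1 ± 4.85 against 37.4 ± 3.66 TPM, a log2 difference of -0.69 (95% interval -0.94 to -0.44) with 0 of 5 vindeburnol libraries above the VB-127 mean and an adjusted p of 0.208.

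No gene passed the test between the compounds: limma called 0 of 16153 genes, and 546 had an unadjusted p under 0.05, where 5% of the genes is 808. Of these, 144 were higher and 402 lower after vindeburnol (26.4% higher), while median-ratio scaling gave 44.0% higher. The balance turned to 404 higher and 123 lower (76.7% higher) with noradrenergic, myelin and granule cell covariates. Random regroupings of these libraries gave a median of 407 genes at that unadjusted p. Npas3 was higher after vindeburnol in 5 of 5 libraries, at 0.69 (95% interval 0.39 to 0.99, adjusted p 0.802). The mitochondrial carrier gene Ucp2 and the small GTPase gene Arl4d were at 0.68 and 1.01, each with an adjusted p of 1.00. On the lower side, Cox8b, the neurotrophic gene Ndnf, the myelin gene Pmp22, the immediate early gene Ier2 and the myelin lipid synthesis gene Ugt8a were at -1.23, -1.02, -0.53, -0.62 and -0.66, with adjusted p between 0.802 and 1.00. For Dbh the difference was -0.43 (95% interval -1.72 to 0.86), for Th -0.47 (95% interval -1.46 to 0.53), for Gfap -0.21 (95% interval -0.56 to 0.14) and for Fos -0.48 (95% interval -1.08 to 0.12), each with an adjusted p of 1.00. These intervals leave room for differences in either direction. Gal, Slc18a2, Ddc, Mbp, Bdnf and Ttr were at -0.10, -0.56, -0.39, -0.23, -0.16 and -0.16, each with an adjusted p of 1.00. Gal turned to 0.02 without VB-127 replicate 2 and Ttr to 0.05 without vindeburnol replicate 1.

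Camera with the preset correlation called 7 of 38 lists between the compounds, 1 higher and 6 lower after vindeburnol, while fry called 0 and the exact permutation test 0. Glucocorticoid-responsive genes were the list called with both correlation settings (adjusted p = 0.0368 with an estimated correlation). All 14 were higher in value, 13 at an unadjusted p under 0.05 and 13 adjusted over the list alone, with 0 over all genes; Cdkn1a, Sgk1, Mt2 and Mt1 were at 1.60, 1.28, 0.55 and 0.38. Without vindeburnol replicate 3 or 4 the adjusted p with an estimated correlation was 0.333 and 0.0608, and without VB-127 replicate 1, 5 or 6 it was 0.0663, 0.0860 and 0.0804, with list means of 0.53 to 0.87 over the libraries left out. Median-ratio scaling also ended this call, with a mean of 0.74 (95% interval 0.30 to 1.19, adjusted p = 0.0819 with an estimated correlation). Without vindeburnol replicates 1 and 3 the mean was 0.35 (95% interval -0.04 to 0.75). Endothelial genes had 5 of 11 adjusted over the list alone (adjusted p = 0.5004 with an estimated correlation), with the receptor genes Tek and Kdr at -0.60 and -0.52 and the transporter gene Slco1c1 at -0.54. Immediate early genes had 2 of 14 adjusted over the list alone (adjusted p = 0.5004 with an estimated correlation), with Ier2, Junb, Arc and Jun at -0.62, -0.57, -0.47 and -0.36. Myelin genes had 1 of 13 adjusted over the list alone (adjusted p = 0.560 with an estimated correlation), with Ugt8a at -0.66 and Aspa at -0.42.

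The remaining 3 lists called lower after vindeburnol than after VB-127 held microglial, noradrenergic and respiratory chain genes. Reactive microglial and MHC genes had a mean of -0.20 with 0 of 12 adjusted over the list alone (adjusted p = 0.5004 with an estimated correlation), with Cd74 at -0.59 and H2-K1 at -0.39. Noradrenergic genes had a mean of -0.23 with 1 of 11 adjusted over the list alone, Qdpr at -0.31 (adjusted p = 0.560 with an estimated correlation). This list's preset call was lost under 17 of 35 alternatives, and without vindeburnol replicate 3 the mean was -0.12. The 35 include the fit with this list as a covariate, which fixes its difference at 0 in advance. Nuclear-encoded respiratory chain genes had a mean of -0.07 with 0 of 19 adjusted over the list alone (adjusted p = 0.923 with an estimated correlation). In none of these lists did a gene pass over all genes tested by limma. The number of lists called was 4 without VB-127 replicate 2, 11 without VB-127 replicate 4 and 12 without vindeburnol replicate 4, and 835 genes had an unadjusted p under 0.05 without vindeburnol replicate 2.

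**Figure D3:**
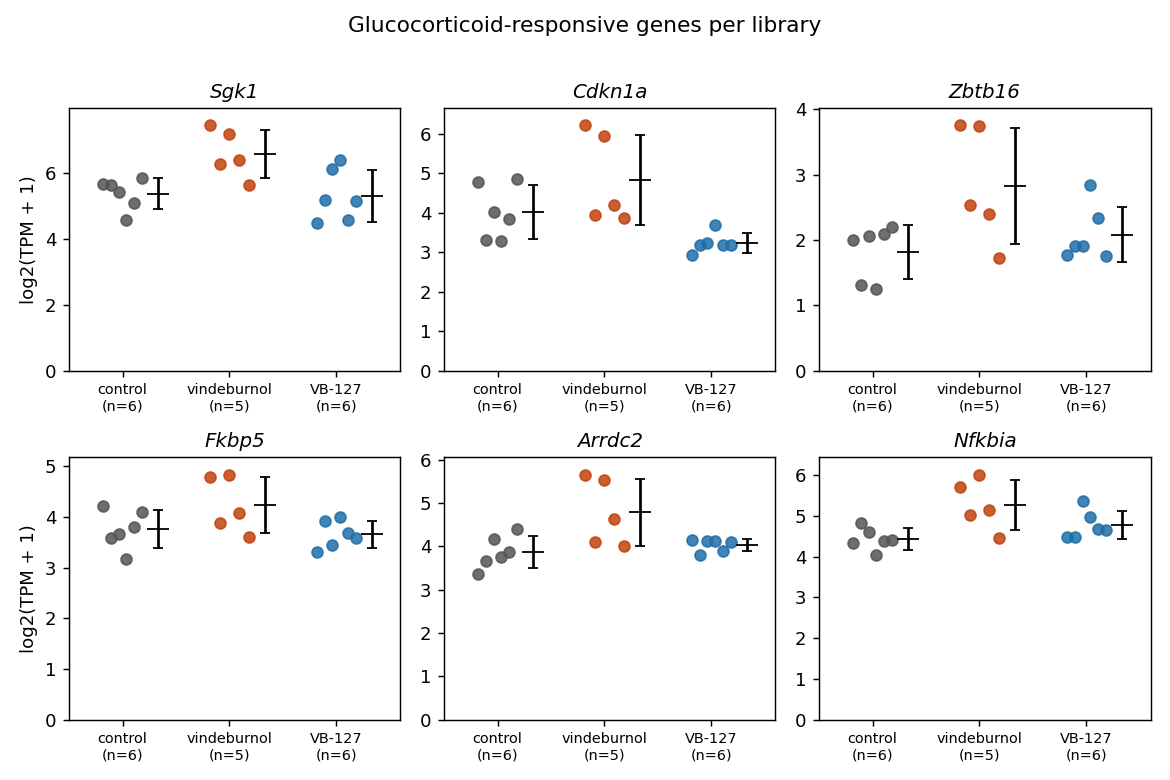
Level of 6 glucocorticoid-responsive genes in each library as log2(TPM + 1), by group; each point is a library, the bar is the mean and the error bar 1 SD. Sgk1 was highest in vindeburnol replicates 1 and 3, at 175 and 146 TPM.

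The differences from controls were set side by side across the 16153 genes, which are not independent replicates. The Pearson correlation between the compounds was 0.591 and the Spearman correlation 0.568. Both share the same controls. Simulated unchanged groups that also shared controls gave a mean Pearson correlation of 0.470 (SD 0.145), with 17 of 100 simulations as high. The simulated controls came from the shuffled deviations of all libraries, so the real controls were not held fixed. The covariance was 0.0294 against a simulated mean of 0.0202 (SD 0.00801). With the controls split between the compounds, the median correlation over 20 splits was 0.111 (0.0270 to 0.202) and the median covariance 0.00787; with the same 3 controls for both compounds they were 0.714 and 0.0507. Signs were the same in 76.9% of genes, against a simulated mean of 66.4%, for which no spread was recorded. Of the genes higher at an unadjusted p under 0.05, 549 were shared, against 108 for independent lists and a mean of 86.8 in simulations, the highest of which was 1168; of the lower genes 25 were shared, against 1.05 and 91.6.

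**Figure D4:**
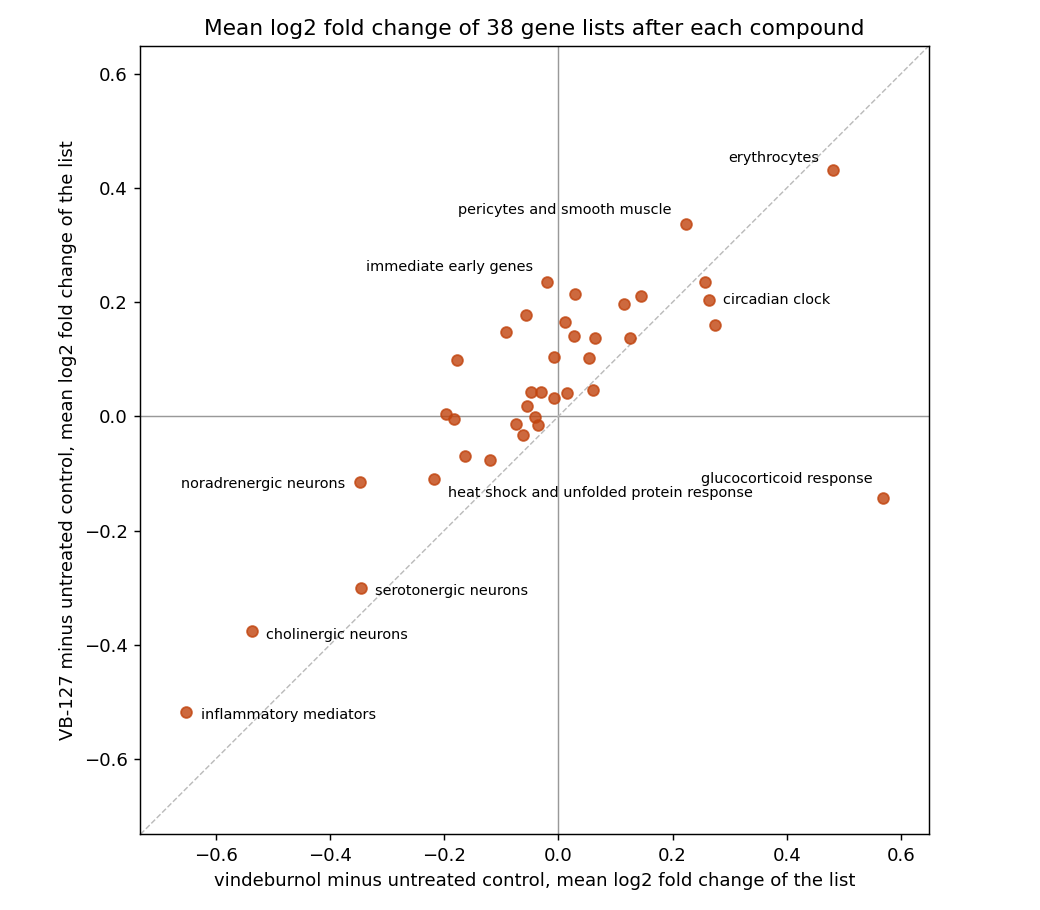
Mean log2 fold change of 38 gene lists after vindeburnol (horizontal) and after VB-127 (vertical), each against untreated controls; each point is a list and the dashed line marks equal values. The glucocorticoid response list lies at 0.57 and -0.14.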

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

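The tests of explanations in this part were chosen only after the results were seen, except for 1 set of covariates said to be planned. A library was singled out where its distance from the nearest of its group was large for the group's range by Dixon's criterion. Of 255 groups of libraries examined, 20 held such a library, where chance gives 5% or 12.75.

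Among single genes, Actb was at 444 TPM in control replicate 1 against 531 to 580 in the other controls. Th was at 17.8 TPM in control replicate 1 against 63.8 to 117. Dbh was at 1.72 TPM in vindeburnol replicate 4 against 0 to 0.228. Smpd2 was at 15.9 TPM in VB-127 replicate 2 against 18.01 to 19.3. Hilpda was at 7.54 TPM in VB-127 replicate 3 against 4.97 to 5.51, and Sdf2l1 at 16.2 TPM in VB-127 replicate 1 against 20.8 to 22.0. Bdnf was at 8.63 TPM in vindeburnol replicate 2 against 4.64 to 5.14. Snrpe was at 81.9 TPM in vindeburnol replicate 2 against 69.0 to 72.0 and at 82.6 TPM in VB-127 replicate 2 against 63.0 to 69.2. Mt1 was at 1263 TPM in vindeburnol replicate 1 against 923 to 1000.0.

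Among mean log2 levels of lists, cholesterol biosynthesis was at 4.98 in vindeburnol replicate 3 against 5.20 to 5.28. Circadian clock genes were at 3.96 in VB-127 replicate 2 against 4.29 to 4.47, and sodium and calcium channel genes at 4.34 in the same library against 4.68 to 4.88. Inflammatory mediators were at 1.32 in vindeburnol replicate 4 against 1.13 to 1.15 and at 2.19 in VB-127 replicate 4 against 1.06 to 1.23. Meningeal fibroblast genes were at 3.13 in VB-127 replicate 6 against 1.69 to 2.22. Oxidative stress genes were at 4.33 in control replicate 4 against 4.61 to 4.70. Control replicate 1 was low for 2 added lists, dopaminergic genes at 2.66 against 3.75 to 4.27 and Edinger-Westphal peptide genes at 2.11 against 5.81 to 6.56. The added noradrenergic-specific list was at 0.55 in vindeburnol replicate 4 against 0.04 to 0.17.

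Of 38 lists, 7 differed between the compounds by camera's preset test of vindeburnol minus VB-127. Their mean log2 differences were 0.71 for the glucocorticoid response, -0.28 for endothelium, -0.26 for immediate early genes, -0.23 for myelin, -0.23 for noradrenergic neurons, -0.20 for reactive microglia and MHC and -0.074 for the respiratory chain. An estimated correlation called 1 of the 7, the glucocorticoid response, while fry called 0 and the exact permutation test 0. Of the 100 regroupings of these libraries, 58 called as many lists as the real 7, with 20 in the highest other, so chance cannot be excluded for the number.

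The glucocorticoid-responsive genes lay 0.71 higher after vindeburnol than after VB-127. The difference was 0.71 (95% interval 0.25 to 1.18) with log2 Bc1 as a covariate and 0.70 (95% interval 0.18 to 1.21) with the dopaminergic, serotonergic and noradrenergic lists, which argues against each of these as the whole cause. With the cerebellar granule and Purkinje lists it was 0.77 (95% interval 0.28 to 1.26). The granule list did not set vindeburnol replicate 3 apart, at 3.70 against 3.01 to 3.71 in the other libraries. This fit therefore argues against a cerebellar share only as far as the Purkinje list follows it. With the planned noradrenergic, myelin and granule cell covariates the difference fell to 0.57 (95% interval 0.05 to 1.09), so a part from tissue stays open, and with an estimated correlation each of these 4 fits ended the call (adjusted p 0.0967, 0.135, 0.0691 and 0.651). Animals that differ among themselves may account for it, since without vindeburnol replicates 1 and 3 the difference was 0.35 (95% interval -0.04 to 0.75), a test that leaves out the highest libraries and cannot decide. In 8 of 100 regroupings at least 1 list passed with an estimated correlation, as in the real split, with 2 in the highest other, so chance is not excluded, and an effect of vindeburnol stays open.

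Dbh lay below the controls after both compounds, by log2 differences of -1.71 (95% interval -3.12 to -0.30) and -1.28 (95% interval -2.62 to 0.06). The 2 libraries with the highest Dbh, control replicates 1 and 6, were also the 2 highest for 2 other noradrenergic genes examined, Slc6a2 and Phox2a, which is consistent with libraries that hold different shares of noradrenergic tissue. Without them the difference was -0.75 for vindeburnol (95% interval -1.69 to 0.20) and -0.32 for VB-127 (95% interval -1.23 to 0.60). An effect of either compound on Dbh cannot be told apart from tissue content, since both intervals cover 0 and also sizeable decreases.

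More genes lay higher than lower after both compounds, 85.1% and 94.8% of those at an unadjusted p under 0.05. With Bc1 left out of the TPM total these became 65.3% for vindeburnol and 80.6% for VB-127. With log2 Bc1 as a covariate, which also takes up whatever else moves with Bc1, they were 55.4% and 76.4%. The share of the total that Bc1 takes may account for part of the excess, and what the remainder comes from stays open. A broad effect of the compounds cannot be told apart from it, since TPM gives values relative to each library's total. Such an effect also cannot be told apart from that of daily gavage, which the untreated controls are not said to have received.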

How the results depend on the processing

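Alternatives chosen after seeing the data were leaving out Bc1, protein-coding genes alone, the covariates other than the set of noradrenergic, myelin and granule cells, the joint omissions of libraries, the same 3 controls for both compounds and the exact permutation test of lists; the rest were planned. Each count of changed genes was run under 35 alternatives and each count of lists under 38; for the counts below the cause was not tested unless stated. For vindeburnol against controls the count of changed genes went from 0 to 1, Npas3, with library weights, without trend and robust moderation, with noradrenergic, myelin and granule cell covariates, without Bc1 and with protein-coding genes alone. For VB-127 against controls the count went from 1 to 0 with a pseudocount of 0.1, with no filter, with noradrenergic, myelin and granule cell covariates, with dopaminergic, serotonergic and noradrenergic covariates, with log2 Bc1 as a covariate and without control 4, VB-127 1 and vindeburnol 3. It was also 0 with at least 5 TPM or protein-coding genes alone, which exclude Gm28119. It was 2 with only the 2 groups compared or without control replicates 1 and 6, and 3 with library weights (Actb, Gm13563 and Gm28119). Leaving out 1 library gave 0 to 1. Between the compounds limma called 0 genes under all 35.

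The number of lists for vindeburnol against controls, 17, became 9 with library weights, 11 with log2 Bc1 as a covariate, and 0 with an estimated correlation, fry or the exact permutation test. For VB-127 against controls 9 became 4 with noradrenergic, myelin and granule cell covariates, 14 with protein-coding genes alone, 0 with an estimated correlation, fry or the exact permutation test, and 7 to 14 with 1 library left out. The noradrenergic list, 1 of the 9, is itself among those covariates, which fixes its difference at 0 in advance. Between the compounds 7 became 4 with median-ratio scaling, without Bc1 or with protein-coding genes alone, 1 with an estimated correlation, 0 with fry or the exact permutation test, and 4 to 12 with 1 library left out. The means of 9 called lists had the opposite sign under at least 1 alternative, 37 values in all, 13 of them for ependymal genes after VB-127, and camera's direction turned in 4. With noradrenergic, myelin and granule cell covariates serotonergic genes were at 0.30 after vindeburnol and ependymal genes at 0.20 after VB-127. With the dopaminergic, serotonergic and noradrenergic covariates cholinergic genes were at 0.10 after vindeburnol. Ribosomal genes after vindeburnol were at 0.033 without vindeburnol replicate 1, and from -0.031 to 0.035 with 1 library left out. The cause was not tested for these. A further 151 list values lost their call without a turn in camera's direction, and 88 gained one. Direction was not compared for those that gained a call. Both counts were taken over alternatives that include a fit with the noradrenergic and myelin lists themselves as covariates. That fit fixes the mean differences of these lists at 0 in advance. The correlation of the compounds fell to a median of 0.111 with the controls split, which leaves 3 controls per difference; with 3 controls shared by both it was 0.714.

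With the replicate number as a block, limma called 0 genes in each comparison, and the count for VB-127 against controls went from 1 to 0. No pairing by number showed in the values: deviations of samples with the same number had correlations of -0.195 to 0.111, and 1 of 17 libraries correlated best with its own number. A shared day or litter is not excluded by this, since other differences between libraries may hide it. TPM gives no depth, so what read depth limits could not be assessed.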

Other observations

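The exact permutation tests, the 4 added lists, the choice of measures and the regrouping tests in this part were chosen only after the results were seen; camera and quantile normalization were planned. Immediate early genes lay higher after VB-127 than in controls in 14 of 14 members, with a mean log2 difference of 0.24 (exact permutation p = 0.0455, adjusted p 0.423). Oligodendrocyte precursor genes lay higher in 9 of 9 members, with a mean of 0.21 (exact permutation p = 0.0476, adjusted p 0.423). The median of all genes was 0.11 in this comparison, camera called neither list (adjusted p 0.175 and 0.269), and the mean of the immediate early genes was 0.10 with quantile normalization. The neutrophil and acute-phase genes of an added list, with Lcn2 among them, had means of -0.96 after vindeburnol and -1.04 after VB-127 (exact permutation p = 0.0844 and 0.0498, adjusted p 0.303 for both). Lcn2 itself was at 126, 60.5 and 46.3 TPM in control replicates 6, 1 and 3, at 1.43 to 12.0 TPM in the other 3, and at 0.63 to 7.00 TPM in the 11 treated libraries. Its exact permutation p was 0.0758 for vindeburnol and 0.0152 for VB-127, with adjusted p of 0.455 and 0.227.

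The neuropeptide S gene Nps had a mean of 1.87 TPM in controls, 0.0347 after vindeburnol and 0.417 after VB-127 (exact permutation p = 0.0281 and 0.0563, adjusted p 0.281 and 0.422). Control replicates 1 and 6 were highest, at 4.03 and 3.28 TPM, 1 vindeburnol library was above 0, at 0.173 TPM, and without VB-127 replicate 2, at 1.51 TPM, the VB-127 mean was 0.198 TPM. Dbh was also highest in these 2 controls, at 18.9 and 12.3 TPM, and in VB-127 replicate 2 within its group, at 2.36 TPM. Among vindeburnol libraries Dbh was highest in replicate 4, where Nps was at 0. An effect of either compound on Nps therefore cannot be told apart from tissue content. The added noradrenergic-specific list had mean differences of -0.86 and -0.69 (exact permutation p = 0.0823 and 0.152, adjusted p 0.303 for both), which were -0.60 and -0.42 without control replicate 1 and -0.64 and -0.47 without control replicate 6. The dopaminergic list was at -0.19 and 0.21 and the Edinger-Westphal peptide list at 0.91 after both compounds, with exact permutation p of 0.561, 0.532, 0.223 and 0.117. Without control replicate 1 the dopaminergic list was at -0.41 and -0.02 and the Edinger-Westphal list at 0.24 after both. The dopaminergic difference for vindeburnol was -0.05 without vindeburnol replicate 3, -0.09 without control replicate 5, -0.12 without control replicate 3 and -0.30 without vindeburnol replicate 4 or 5, and for VB-127 0.10 without VB-127 replicate 1 and 0.34 without VB-127 replicate 3. The number of genes above 0 TPM was 24295 on average after VB-127 and 22647 in controls (exact permutation p = 0.0130, adjusted p 0.227). This number depends on read depth, which is unknown, so it cannot be told apart from a difference in depth. The transcription factor gene Otx2 ranged from 4.27 to 27.1 TPM, and Slc17a7, a vesicular glutamate transporter gene, reached 59.8 and 53.6 TPM in control replicates 6 and 4 with a median of 4.97 TPM over the 17 libraries.

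The libraries were also regrouped at random, with 100 regroupings per comparison and the real one included. For vindeburnol against controls, 29 gave as many genes at an unadjusted p under 0.05 as the real 1319, with 4958 in the highest other, so chance cannot be excluded. All 100 gave at least the real 0 called genes, an outcome fixed by a count of 0 that says nothing, with 737 in the highest other. That split, of vindeburnol replicates 1, 2 and 4 and control replicates 3 and 6 against the other 6, points to a structure of the samples that the groups do not describe; Bc1 took 16.1% to 22.5% on its first side and 22.4% to 35.3% on the other. As many lists as the real 17 were called in 4, with a median of 8 in the others and 20 in the highest other. That share is under 0.05 only without adjustment for the other counts tested this way. It rests on a draw of 100 from 462 possible splits, so it is itself uncertain and does not firmly exclude chance. The number of lists called was 0 with an estimated correlation, fry or the exact permutation test. For VB-127 against controls, 6 gave at least the real 1 called gene, with 5 in the highest other, 12 gave as many genes as the real 1648, with 4008 in the highest other, and 30 gave as many lists as the real 9, with 15 in the highest other. Between the compounds, 31 gave as many genes as the real 546, with 2622 in the highest other. Chance cannot be excluded for any of these 4 counts. The 100 that gave at least the real 0 called genes between the compounds, with 1 in the highest other, again say nothing.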
